A study of Homo sapiens with 6 samples.

How the data were processed

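Expression was measured by RNA sequencing in 2 human esophageal adenocarcinoma cell lines, Eso26 and OE33, each transfected with a non-silencing siRNA (control) or with an siRNA against PPARG (siPPARG). PPARG binding was measured in both lines by chromatin immunoprecipitation and sequencing (ChIP-seq). Per the labels, Eso26 was grown in RPMI-1640 and OE33 in DMEM, so medium and line cannot be separated. The 6 samples fall into 6 groups of 1, taken from the sample titles. The series' design text speaks of triplicates, but each count table holds 1 column per condition; whether a column is a single library or a sum is not given in the sources used here. Each column was treated as 1 library.

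The deposited expression values are raw counts per gene, whole numbers with a different total in each library, without normalisation per the file headers and values. The submitters' processing notes name the tools Trim Galore, STAR, Bowtie, Picard and MACS2 and the genome build hg19, without saying which tool made which file; the read counter, its strand setting, its treatment of multi-mapping reads and the annotation version are not given in the sources used here. Each table has 37533 rows, in the same order for both lines; 40 rows repeat an Ensembl identifier and were summed with their partner, leaving 37493 identifiers. Of these, 37402 matched the identifier-to-symbol table used here. Gene symbols are those of the count tables. No column of another sample was present.

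Each peak list comes as 1 narrowPeak table per line, with the fold enrichment (a ratio) of each peak computed by the authors' caller. The −log10 p and −log10 q of each peak were likewise given by the authors' caller, and the lowest −log10 q was 2.05 in Eso26 and 2.02 in OE33. The control library used for calling, the treatment of duplicates and whether replicates were pooled are not given in the sources used here. Peak coordinates are on hg19, with starts converted to count from 1. The peak names in the lists contain the word bwa, an aligner that the submitters' processing notes do not name, so the aligner behind the peak lists is not settled. No hg19 annotation was used here, so peaks were not assigned to genes, and the planned comparison of expression between genes with and without a PPARG peak was not run.

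Within each line, counts were scaled with TMM factors (edgeR 4.0.16, R 4.3.3), and the log2 fold of siPPARG against control was the difference of log2 CPM (counts scaled to a common library total) with a prior count of 2. Genes at 5 CPM or more in at least 1 of the 2 libraries were kept. With 1 library per condition no test within a line is possible: genes are described by size, with 2-fold as the threshold. For ratios of named genes, an exact conditional binomial (Clopper-Pearson) 95% interval was computed from the counts, and for CPM an exact Poisson 95% interval. These intervals cover counting error only, not the spread between cultures. A count of 0 allows up to 3 counts, which is between 0.132 and 0.177 CPM in these libraries. Library totals ran from 16866996 to 23019840 counts.

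Gene lists (23, among them fatty acid and cholesterol synthesis, PPAR targets, epithelial programmes, cell cycle, interferon, stress pathways and markers of squamous, mesenchymal, immune and fat cells) were fixed before the data were examined, as were the tests of the comparisons, the rule for named genes and all alternatives except those named as added later. The median log2 fold of a list's kept members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A percentile outside the central 95% describes where the list stood in these libraries; it is not a p-value, and members of a pathway are not independent. The 20 lists with at least 3 kept members in both lines were read this way.

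An effect common to both lines was tested with edgeR's quasi-likelihood test in a model with cell line and treatment on the 4 libraries, which leaves 1 residual degree of freedom. Adjusted p-values are Benjamini-Hochberg. DESeq2 1.42.0 (Wald test) and limma 3.58.1 (voom) were alternatives. A difference of effect between the lines cannot be tested with these libraries. On counts simulated from the real means and library sizes with 1 common dispersion, the shared fit recovered 98% of 100 genes changed 2-fold and 100% of 100 changed 4-fold, and called 8 unchanged genes of 11343 tested. Each simulated change was of the same size in both lines. Real genes vary in dispersion and can change in 1 line alone, so this is the best case.

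Peaks were called shared at an overlap of at least 1 bp (counts checked with bedtools 2.31.1). The overlap was set against 100 shuffles of the Eso26 list within each chromosome, whose length was taken as the largest peak end. Shares carry Wilson 95% intervals.

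Named genes were PPARG and the factors ELF3, KLF5, GATA6 and EHF; up to 4 members of each list with the largest absolute log2 fold in either line; the 10 highest and the 10 lowest log2 folds per line among kept genes with an official symbol and at least 100 counts in the higher library; the 10 per direction with the same sign in both lines and the largest value of the smaller absolute log2 fold; and the 5 strongest peaks per line. The text prints part of the genes this rule names, and 1 result is not reported here. Alternatives were other scalings (RLE, library size, upper quartile), other expression filters, other prior counts, a 1.5-fold threshold, list means in place of medians, other tools for the shared fit, and other peak thresholds and overlap rules.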

Results

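The data comprised 4 RNA-seq libraries and 2 PPARG ChIP-seq peak lists from the esophageal adenocarcinoma cell lines Eso26 and OE33. PPARG is a nuclear receptor that activates lipid genes, and the study's title places it in a loop with master regulator transcription factors and fatty acid synthesis. The total counts were 23019840 in the Eso26 control, 20534170 in Eso26 siPPARG, 16866996 in the OE33 control and 18163767 in OE33 siPPARG. After the expression filter, 10443 genes were kept in Eso26 and 10527 in OE33. Each condition had 1 library, so values within a line have no replicate check, and all intervals below are counting intervals at 95%.

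The comparison of siPPARG with control asks which genes depend on PPARG in each line, and PPARG itself (ENSG00000132170) is its first check. PPARG was far lower after siPPARG in OE33 and nearly equal in the 2 Eso26 libraries. In OE33 it went from 2156 counts (127 CPM, interval 122 to 133) in the control to 313 counts (17.3 CPM, interval 15.4 to 19.3) in siPPARG, which is 7.37-fold lower (interval 6.54 to 8.32). In Eso26 the control held 259 counts (11.4 CPM, interval 10.1 to 12.9) and the library labelled siPPARG held 201 (9.64 CPM, interval 8.35 to 11.1). The Eso26 ratio of siPPARG to control was 0.843, and its interval of 0.698 to 1.02 includes no change. A reduction of PPARG mRNA in Eso26 was therefore not detectable at this depth, while a reduction of the size seen in OE33 lies outside the interval. Directions given below for Eso26 refer to the library labelled siPPARG.

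The epithelial transcription factors KLF5, GATA6, EHF and ELF3 were all lower in OE33 siPPARG, none of them past 1.5-fold. In these libraries, a response to the siRNA itself cannot be told apart from loss of PPARG. KLF5 stood at 0.690 times the control (interval 0.656 to 0.725) and GATA6 had a log2 fold of -0.51 (interval of the ratio 0.606 to 0.807). EHF stood at 0.859 (interval 0.833 to 0.886) and ELF3 at 0.899 (interval 0.869 to 0.929). The median log2 fold of these factors was -0.37 in OE33, at percentile 0.41 of random lists. In Eso26 the same median was -0.029, or 0.016 without a scaling factor, with ELF3 at 1.17 times the control (interval 1.13 to 1.22), EHF at 0.894 (interval 0.846 to 0.944), KLF5 at 0.940 (interval 0.887 to 0.996) and GATA6 at 1.02 (interval 0.939 to 1.11).

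**Figure D1:**
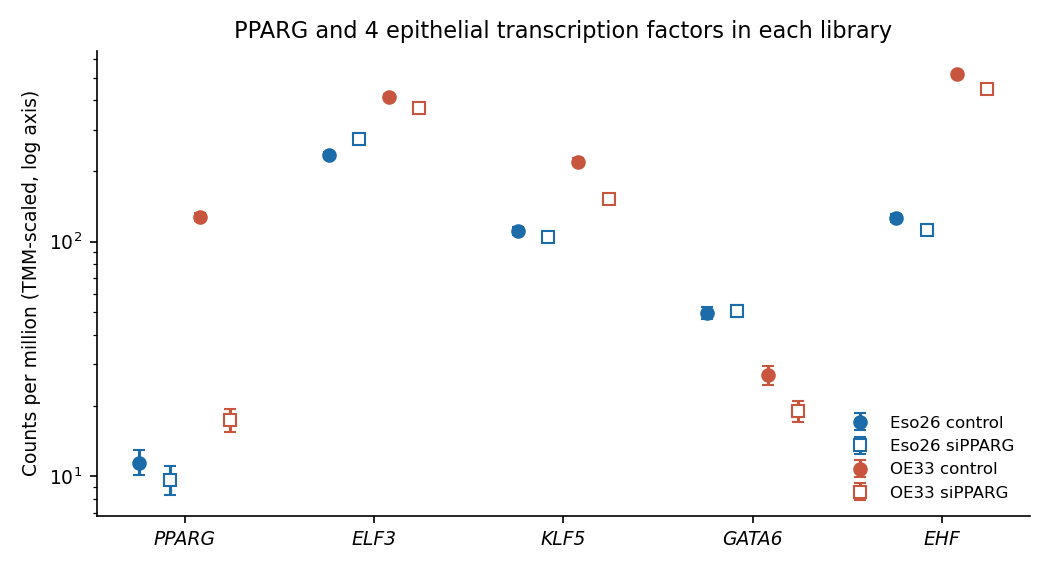
TMM-scaled CPM (log axis) of PPARG, ELF3, KLF5, GATA6 and EHF in each of the 4 libraries; filled circles are controls, open squares siPPARG, bars are exact Poisson 95% intervals. PPARG went from 127 to 17.3 CPM in OE33 and from 11.4 to 9.64 CPM in Eso26.

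In OE33, the largest differences after siPPARG were higher interferon-response genes and lower PPARG, with lower mitotic genes as a broad smaller shift. Past 2-fold, 110 genes were higher and 44 lower; without an expression filter the balance turned, with 547 higher and 584 lower. All 30 kept members of the interferon list were higher in siPPARG, 20 of them past 2-fold, with a median log2 fold of 1.37 at percentile 100 of random lists. RSAD2, which encodes the antiviral enzyme viperin, went from 470 to 3448 counts, 6.86-fold higher (interval 6.23 to 7.57). BST2 (tetherin) was 6.42-fold higher (interval 5.43 to 7.65), MX2 4.73-fold (interval 4.33 to 5.18) and IFIT3 4.67-fold (interval 4.47 to 4.89). Among the 10 highest log2 folds in OE33 were also those of ZBP1, a sensor of Z-form nucleic acids, which was 9.24-fold higher (interval 6.16 to 14.4), TRIM22 (7.35-fold), IFITM1 (5.72-fold), BATF2 (5.47-fold), RELN (5.05-fold) and PDCD1LG2 (4.86-fold). IFIT and IFITM genes have close relatives, and how shared reads were counted is not known.

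Inflammatory genes were also higher in OE33 siPPARG. Of 17 kept members of the NF-kB list, 14 were higher and 3 were past 2-fold, with a median log2 fold of 0.43 at percentile 100. The chemokine genes CXCL5, CXCL2 and CXCL8 were 4.48-fold (interval 3.16 to 6.50), 2.28-fold (interval 2.10 to 2.48) and 2.07-fold (interval 1.99 to 2.16) higher, and TNFAIP3, a feedback inhibitor of NF-kB, 1.84-fold (interval 1.78 to 1.90). The hypoxia and glycolysis list had 21 of 24 members higher and a median of 0.21, at percentile 100, led by ADM, which encodes the peptide adrenomedullin, at 2.16-fold (interval 1.88 to 2.48), EGLN3 at 1.83-fold (interval 1.56 to 2.16) and NDRG1 at 1.65-fold (interval 1.60 to 1.71). Of the stress list, 16 of 23 were higher and the median was 0.13, at percentile 99.4. Its largest differences were ATF3 at 1.64-fold (interval 1.42 to 1.91), TRIB3 at 1.54-fold (interval 1.46 to 1.63) and the chaperone gene HSPA5 at 1.40-fold (interval 1.37 to 1.44).

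All 26 genes of the mitotic list were lower in OE33 siPPARG, each with a counting interval below 1, although 1 of them was past 1.5-fold. The median log2 fold was -0.38, at percentile 0 of random lists. HMMR, a spindle-associated protein gene, stood at 0.589 times the control (interval 0.552 to 0.628), KIF20A at 0.687 (interval 0.628 to 0.752) and the mitotic kinase gene PLK1 at 0.701 (interval 0.665 to 0.739), and BUB1B had a log2 fold of -0.51 (interval of the ratio 0.647 to 0.759). Of the DNA replication list, 22 of 26 genes were lower with a median of -0.14, at percentile 0.26. CDT1 stood at 0.754 (interval 0.680 to 0.836) and MCM7 at 0.793 (interval 0.772 to 0.813).

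The lipid lists stood mostly within the range of random lists in OE33. Of 21 kept fatty acid synthesis genes, 13 were lower and 8 higher, 1 was past 1.5-fold, and the median log2 fold of -0.057 stood at percentile 19.3, within the range of random lists. Counting intervals lay below 1 for 7 members and above 1 for 4. FASN (fatty acid synthase) went from 5963 to 4858 counts, 0.762 times the control (interval 0.733 to 0.791), ACACA (acetyl-CoA carboxylase) stood at 0.778 (interval 0.749 to 0.808), SCD at 0.783 (interval 0.768 to 0.799) and SCD5, the other human stearoyl-CoA desaturase gene, at 0.619 (interval 0.540 to 0.709). FADS3 was 1.29-fold higher (interval 1.09 to 1.52). Of 20 fatty acid oxidation genes, 17 were lower with a median of -0.12, at percentile 2.97; the mean of -0.17, at percentile 0.5, lay outside the range of random lists. Of 22 oxidative phosphorylation genes, 18 were lower with a median of -0.13, at percentile 1.26; the mean of -0.11, at percentile 3.02, lay within the range of random lists.

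Textbook PPAR targets went both ways in OE33. Of 18 kept members, 13 were lower and 5 higher, with a median of -0.065 at percentile 16.2. AQP3, an aquaglyceroporin gene, stood at 0.566 times the control (interval 0.549 to 0.583) and IMPA2 at 0.701 (interval 0.607 to 0.810). ANGPTL4 went the other way, from 100 to 197 counts, 1.84-fold higher (interval 1.44 to 2.37). The cholesterol list had a median of -0.073 (percentile 10.9), with HMGCS1 1.47-fold higher (interval 1.39 to 1.55) and FDFT1 at 0.777 (interval 0.742 to 0.815). Among lipid regulators, INSIG1 was 1.62-fold higher (interval 1.49 to 1.75) and PPARD 1.48-fold (interval 1.41 to 1.55), with a list median of -0.053 at percentile 21.9 and a mean of 0.043. Of the triglyceride list, 10 members were higher and 10 lower (median 0.011, percentile 60.6).

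The epithelial lists in OE33 held a few large differences. The carcinoembryonic adhesion genes CEACAM5 and CEACAM6 stood at 0.257 (interval 0.230 to 0.287) and 0.330 (interval 0.306 to 0.355) times the control; they are close paralogs. SPINK1 was 3.52-fold higher (interval 2.63 to 4.77). The columnar list as a whole had a median of -0.081 (percentile 11.4), within the range of random lists, and a mean of -0.18 outside it (percentile 1.04). In the squamous list, KRT13 stood at 0.181 (interval 0.120 to 0.266) while KRT16 was 2.03-fold (interval 1.68 to 2.47) and SPRR1B 1.94-fold (interval 1.64 to 2.30) higher, so that the median of 0.32 (percentile 99.5) and the mean of -0.047 differ in sign. Among 16 other gastrointestinal factors the median was -0.097 (percentile 9), and NR5A2, a nuclear receptor gene, stood at 0.395 (interval 0.298 to 0.519). The p53 list (median 0.065, percentile 86.2) and the reference genes (median 0.059, percentile 85.9) stood within the range of random lists. The immediate early list had 8 members higher and 8 lower, with a median of 0.028 (percentile 72.4) and a mean of -0.13. The others among the 10 lowest log2 folds were CST4, EGR1, TRIM31, PRKACB, BHLHE41, OIP5-AS1 and NRAS, with log2 folds from -2.36 to -1.61; OIP5-AS1 is an antisense transcript and the strand setting of the counting is not known. Of the markers of other cell types, the mesenchymal list kept 2 genes in each line, the immune list 1, and the fat cell list 1 in Eso26 and 2 in OE33. Kept genes included the fibronectin gene FN1 in OE33 (11633 and 15010 counts in control and siPPARG) and LYZ in Eso26 (571 and 527 counts).

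**Figure D2:**
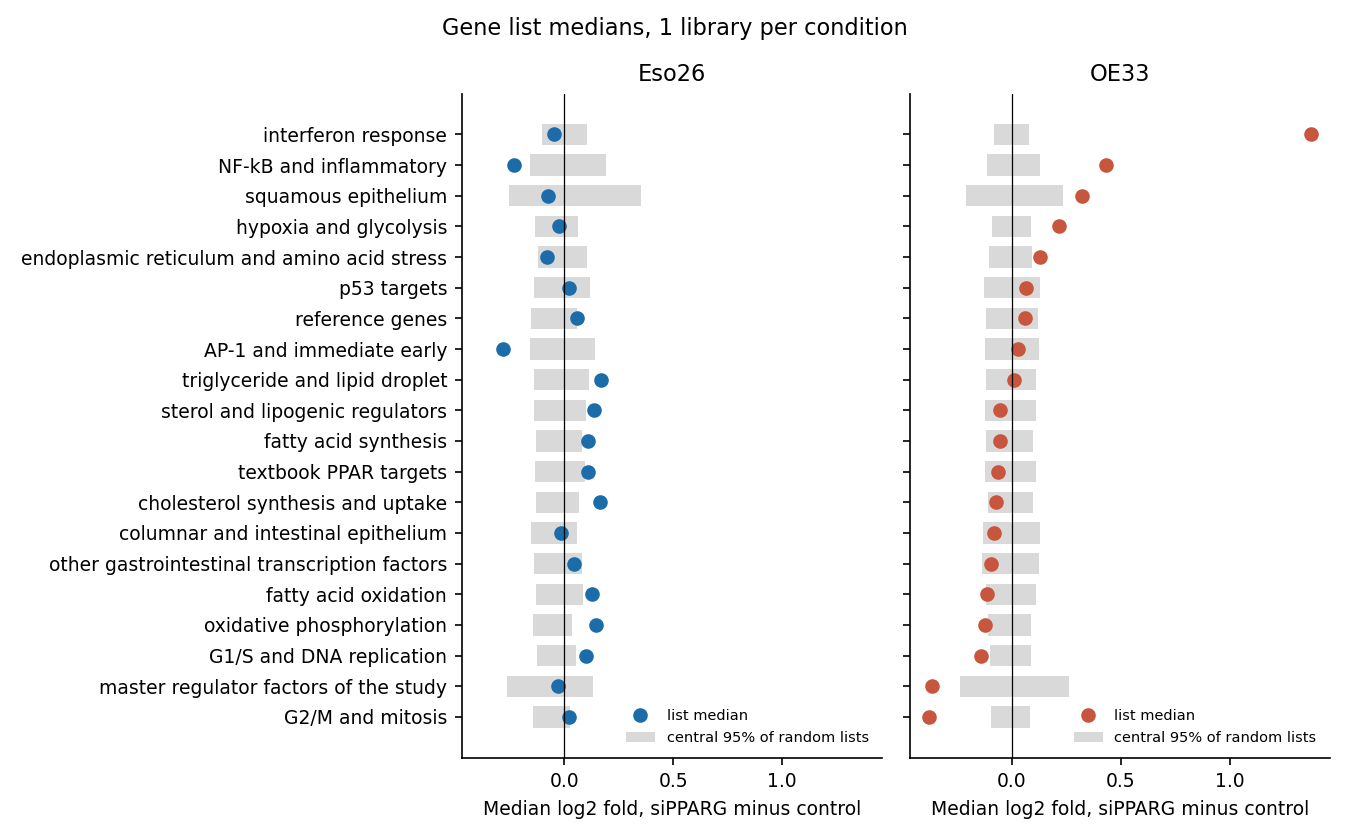
Median log2 fold (siPPARG minus control) of 20 gene lists in Eso26 (left) and OE33 (right); grey bars span the central 95% of 10000 random lists matched on expression. In OE33 the interferon list stood at 1.37 and the mitotic list at -0.38; in Eso26 they stood at -0.049 and 0.023.

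In Eso26, 6 genes were higher and 15 lower past 2-fold, or 8 and 10 without a scaling factor. The balance turned with weaker filters or a lower threshold, with 66 higher and 38 lower at 1 CPM, 713 and 334 without a filter, and 131 and 120 past 1.5-fold, but not at 10 CPM, with 2 higher and 8 lower. Of the immediate early list, 2 genes were lower past 2-fold. EGR1, an immediate early transcription factor gene, went from 845 to 371 counts, 0.477 times the control (interval 0.421 to 0.540), and AREG, which encodes the EGF-receptor ligand amphiregulin, stood at 0.489 (interval 0.452 to 0.529). FOSL1 stood at 0.609 (interval 0.501 to 0.739) and IER3 at 0.680 (interval 0.590 to 0.783). Of 13 kept members of that list, 10 were lower, and the median log2 fold was -0.28, at percentile 0.02. The NF-kB list had 9 of 11 members lower and a median of -0.23, at percentile 0.305. Its largest differences were the apoptosis inhibitor gene BIRC3 at 0.474 (interval 0.428 to 0.524) and CCL20 at 0.654 (interval 0.499 to 0.852). The lowest log2 folds were those of HMGA2, CEACAM6, EMP1, TGFBI, CREB5, TRPV3, ANXA1, BIRC3, EGR1 and CYP4F3. HMGA2 stood at 0.393 (interval 0.280 to 0.545), CEACAM6 at 0.403 (interval 0.288 to 0.556), EMP1 at 0.441 (interval 0.353 to 0.547), TGFBI at 0.447 (interval 0.337 to 0.586), CREB5 at 0.465 (interval 0.396 to 0.545) and the annexin gene ANXA1 at 0.473 (interval 0.438 to 0.510).

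The metabolic lists in Eso26 were slightly higher in the library labelled siPPARG. Of the 20 lists read in each line, 10 lay outside the central 95% of random lists in Eso26 and 9 in OE33. By chance 5% would be expected, so a place outside that range does not single out the metabolic lists. Of 20 fatty acid synthesis genes, 14 were higher, none past 1.5-fold, with a median of 0.11 at percentile 99.4. SCD was 1.31-fold higher (interval 1.28 to 1.35), ACSS2 1.31-fold (interval 1.19 to 1.45), and ME1 stood at 0.715 (interval 0.680 to 0.752). The cholesterol list had 17 of 23 members higher and a median of 0.17 (percentile 99.99), with TM7SF2 at 1.60-fold (interval 1.38 to 1.86) and FDFT1 at 1.48-fold (interval 1.45 to 1.52). Of 21 fatty acid oxidation genes, 19 were higher, with a median of 0.13 (percentile 99.7); ACADS was 1.67-fold (interval 1.47 to 1.89) and CPT1A, which starts the import of fatty acids into mitochondria, 1.54-fold (interval 1.34 to 1.76) higher. PPARA, the related receptor gene, went from 1084 to 1935 counts, 1.94-fold higher (interval 1.80 to 2.09), and SREBF1 was 1.43-fold higher (interval 1.34 to 1.53); their list had a median of 0.14 (percentile 99.5). Of 16 textbook PPAR targets, 12 were higher (median 0.11, percentile 98.5), and the triglyceride list, with 10 members higher and 7 lower, had a median of 0.17 (percentile 99.7) but a mean of 0.074 within the range of random lists (percentile 95.2). Oxidative phosphorylation (20 of 22 higher, median 0.15, percentile 100) and DNA replication (21 of 26 higher, median 0.10, percentile 99.9) were also higher. Beside these shifts, the reference genes had a median of 0.058 in Eso26, at percentile 97.3. The interferon list stood within the range of random lists in Eso26 (12 of 27 higher, percentile 16.0). So did the mitotic list (16 of 26 higher, median 0.023, percentile 97.1), with a mean of -0.0089, the stress list (median -0.080, percentile 9.06), the p53 list (median 0.022, percentile 66.0), the other gastrointestinal factors (median 0.044, percentile 89.9) and the squamous list of 4 genes (median -0.075, percentile 21.8). The columnar list (median -0.016, percentile 67.7) and the hypoxia list (median -0.025, percentile 55.6) lay within the range as well. TP53INP1, a p53 target, had the highest log2 fold (1.42), from 59 to 148 counts, followed by C10orf99, DEGS2, CCDC88B, GPRC5B and FIBCD1 at 2.02-fold to 2.42-fold.

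Across both lines, only a small set of genes was shared, and few passed 2-fold in Eso26 at all. PPARG mRNA was not detectably reduced in Eso26, so a difference shared by both lines cannot be attributed to loss of PPARG. Of the 9588 genes kept in both lines, 12 were lower and 4 higher past 2-fold in Eso26, and 25 and 55 in OE33. CEACAM6, HMGA2 and EGR1 were lower past 2-fold in both, against 0.0313 expected if the lists were independent. In the other direction, 0 genes were higher past 2-fold in both, against 0.0229 expected. CEACAM5 was under the expression filter in Eso26, where it went from 67 to 29 counts. HMGA2, an architectural chromatin protein gene, went from 2414 to 1160 counts in OE33 and from 141 to 51 in Eso26. Past 1.5-fold, 11 genes were lower in both (1.99 expected) and 4 higher in both (1.82 expected), while 6 went in opposite directions. Also lower in both lines were the arginine transporter gene SLC7A2 (log2 fold -1.02 in Eso26 and -0.98 in OE33), FAM135A (-0.85 and -0.74), DPY19L1 (-0.74 and -0.80), CACNA2D1 (-0.75 and -0.72), ACVR2B (-0.77 and -0.70), AQP3 (-0.64 and -0.82) and GULP1 (-0.64 and -0.64). Higher in both were SYNPO (0.74 and 1.98), the innate immune adaptor gene MYD88 (0.75 and 0.70), the immunoproteasome gene PSMB9 (0.63 and 0.86) and NDRG1 (0.62 and 0.72). Over these 9588 genes, the log2 folds were almost unrelated, with a Pearson correlation of 0.041 and a Spearman correlation of 0.027 across genes, which are not independent replicates.

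In the fit of the 4 libraries with cell line and treatment, edgeR's quasi-likelihood test called 0 of 11382 genes at an adjusted p under 0.05; the smallest adjusted p was 0.434, for CEACAM6. By edgeR 575 genes had an unadjusted p-value under 0.05, against 569.1 expected by chance. The residual of this fit is the difference of effect between the lines, so a response in OE33 alone counts as spread. PPARG was not detectably reduced in Eso26, so 0 calls do not show that loss of PPARG was without effect. DESeq2 called 13 genes, 11 lower and 2 higher, and limma-voom called 0. All 13 had the same sign in both lines, but a fit of a common effect favours such genes, so this is no separate sign of agreement. With DESeq2 the log2 fold of CEACAM6 was -1.48 (adjusted p 3.32e-07), that of HMGA2 -1.22 (adjusted p 0.000111), that of DPY19L1 -0.76 (adjusted p 0.00203), that of CEACAM5 -1.61 (adjusted p 0.00397), that of EGR1 -1.58 (adjusted p 0.00529) and that of NDRG1 0.69 (adjusted p 0.00611). TGM2, named after its values were seen, had a DESeq2 log2 fold of 1.29 (adjusted p 0.00240). It went from 1472 to 3799 counts in OE33 and from 5 to 12 in Eso26, where its ratio of 2.61 has an interval of 0.855 to 9.45. The smallest adjusted p of the other edgeR and limma settings ran from 2.34e-05 without an expression filter to 0.469 with limma-voom. With edgeR's p-values adjusted over the list alone, 15 genes in 6 of the 23 lists passed 0.05, against 0 over all genes tested; 7 of them were in the immediate early list, and 0 were in the fatty acid synthesis list of 22 tested genes. Of the 15, 7 were under the expression filter in 1 line, so their calls do not show an effect in both: KRT13 had 0 counts in both Eso26 libraries, SPINK1 had 1 and 5 there, and LGALS4, named after its values were seen, had 2 and 4 in OE33.

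**Figure D3:**
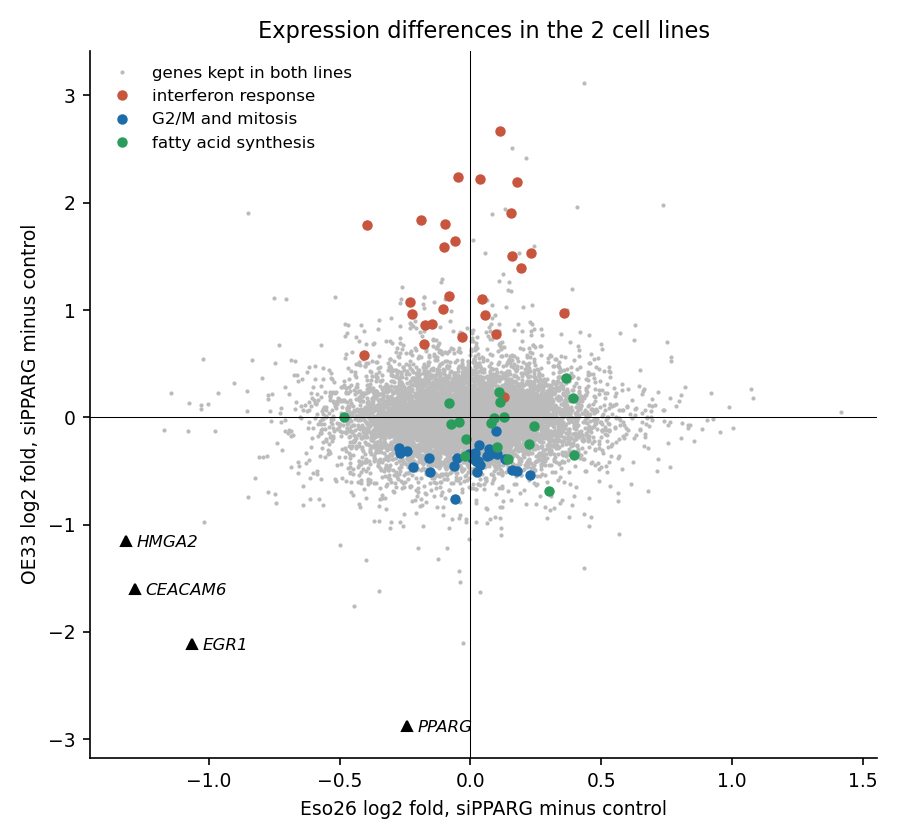
Log2 fold (siPPARG minus control) in Eso26 (x) and OE33 (y) of the 9588 genes kept in both lines; coloured points are members of 3 lists, labelled triangles are PPARG, CEACAM6, HMGA2 and EGR1. The interferon list had a median of 1.37 in OE33 and -0.049 in Eso26, and CEACAM6, HMGA2 and EGR1 lie low on both axes.

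The ChIP-seq lists held 7010 PPARG peaks in Eso26 and 9652 in OE33. Median peak widths were 371 bp and 368 bp, covering 2912 kb and 4462 kb. Within the Eso26 list the fold enrichment given by the authors' caller had a median of 7.38 and a maximum of 43.6; within the OE33 list the median was 6.71 and the maximum 79.1. Each list has its own scale, so these values rank peaks within a list only. The strongest Eso26 peak lay on chromosome 16 from 27334103 to 27334826 (hg19, −log10 q of 109.6), and the strongest OE33 peak on chromosome 7 from 128694503 to 128695651 (−log10 q of 224.6). Overlapping peaks on chromosome 7 ranked among the 5 strongest of both lists: the third in Eso26, from 95237999 to 95238547, and the second in OE33, from 95237486 to 95239222. Each of the 5 strongest OE33 peaks overlapped some Eso26 peak. The Eso26 peaks ranked 1, 2 and 3 overlapped some OE33 peak, and those ranked 4 and 5 did not. The fourth strongest OE33 peak lay on an unplaced contig, and 31 Eso26 and 93 OE33 peaks lay on an unlocalised contig of chromosome 9. Each line had 1 list, so the numbers of peaks have no replicate check.

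Most PPARG peaks were found in 1 of the lists. Of the Eso26 peaks, 1305 (18.6%, Wilson interval 17.7% to 19.5%) overlapped an OE33 peak by at least 1 bp, and 1304 OE33 peaks (13.5%, Wilson interval 12.8% to 14.2%) overlapped an Eso26 peak. Shuffled positions gave a mean overlap of 43.1 peaks and at most 59, so the observed number was 30.3 times the shuffled mean; shuffling ignores mappability and open chromatin. With each list ordered by fold enrichment into 5 groups of nearly equal size, the share had no steady trend with strength. From weakest to strongest it was 20.5%, 14.8%, 16.7%, 16.9% and 24.3% in Eso26 and 13.2%, 13.0%, 12.8%, 9.43% and 19.1% in OE33. The share depended on the overlap rule, and was 7.62% of Eso26 peaks when at least 0.5 of each peak had to be covered.

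**Figure D4:**
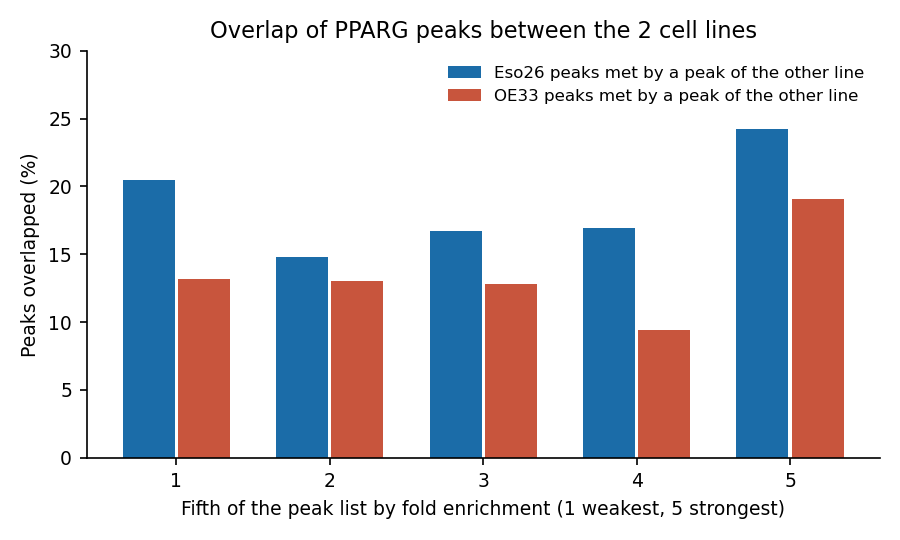
Share of PPARG peaks (%) overlapped by a peak of the other cell line, for 5 equal groups of each list ordered by fold enrichment from weakest (1) to strongest (5). Shares ranged from 14.8% to 24.3% in Eso26 and from 9.43% to 19.1% in OE33.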

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

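The test on leukocyte markers was set before its value was seen; the other tests in this part were chosen after the result was seen.

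Gene lists outside the range of random lists on opposite sides in the 2 lines drew attention; with 1 library per condition the difference between the lines was not tested. The DNA replication list had a median log2 fold of 0.10 in Eso26 and -0.14 in OE33. The NF-kB list had a median of -0.23 in Eso26 and 0.43 in OE33. The oxidative phosphorylation list had a median of 0.15 in Eso26 and -0.13 in OE33, where its mean lay within the range of random lists (percentile 3.02).

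Interferon genes were higher in OE33 siPPARG. A scaling factor shifts all genes alike, so it does not account for a list median 1.31 above that of the reference genes (log2), with a lower quartile of 0.96 against their upper quartile of 0.13. Leukocyte RNA does not account for it either: summed counts of 12 leukocyte markers went from 151 to 165, a ratio of at most 1.28 against a median ratio of 2.59 for the interferon list, and PTPRC went from 0 to 1 count. A response to the siRNA duplex rather than to the loss of PPARG stays open. The same list had a median of -0.049 in Eso26, but PPARG was not detectably reduced there, so neither uptake nor sensing of the duplex in Eso26 is known, and duplex and loss of PPARG cannot be told apart.

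PPARG mRNA was nearly equal in the 2 Eso26 libraries. Too few reads is argued against by the lower counting bound of 0.698 for the ratio, above the OE33 ratio of 0.136. A single library deposited as both columns is argued against by a chi-square of 16.3 per degree of freedom over 11289 genes (31.2 in OE33). Of 62 genes kept in both lines and past 2-fold in OE33, PPARG and the interferon list left out, 64.5% moved the same way in Eso26 (exact interval 51.3% to 76.3%): 18 of 24 lower genes (53.3% to 90.2%) and 22 of 38 higher genes (40.8% to 73.7%). Exchanged Eso26 labels would turn the PPARG ratio over to 1.19 (interval 0.982 to 1.43), so an exchange would not account for the near equality. Whether the labels are exchanged is a separate question. The lower genes argue against it, but the higher genes do not depart from an even split. The genes are also not independent, so an exchange stays open. A weak knockdown, or one that acted on protein more than on mRNA, was not tested and stays open too.

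The mitotic list was lower in OE33, with a median log2 fold that differed from that of the reference genes by -0.44 and an upper quartile of -0.34 against their lower quartile of -0.092, a distance that no scaling factor gives. Slower cycling that goes with the interferon response may be a separate event from the loss of PPARG. In Eso26, with neither higher interferon genes nor a detectable loss of PPARG, the list's median was 0.023, so the origins cannot be told apart: no line holds 1 of them without the other.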

How the results depend on the processing

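Scaling (RLE, library size, upper quartile) left the log2 fold of PPARG and the numbers of genes past 2-fold in the same range in both lines, and so did the prior count for these numbers. The expression filter and threshold, which by construction admit more or fewer genes, moved the numbers. In Eso26 the 21 genes became 1047 without a filter, 104 at 1 CPM, 10 at 10 CPM and 251 at 1.5-fold. In OE33 the 154 became 1131 without a filter, 289 at 1 CPM and 594 at 1.5-fold. The number past 1.5-fold with the same sign in both lines was 15, against 3 past 2-fold. The shared fit called 0 genes in the main setting, 42 without a filter, 1 at 10 CPM and 13 with DESeq2; the cause was not tested. Of 184 alternative list values (means, or medians under other scalings), 182 moved by less than the distance from the middle to the edge of the range of random lists. Other scalings shift all genes of a line nearly alike, so they could hardly move a median further. A list could also cross the edge of the range and still count among the 182. The mean of the squamous list in OE33 was -0.047 against a median of 0.32, with KRT13 as the lowest member, and the immediate early list in OE33 had a mean of -0.13 against a median of 0.028. With means, the triglyceride list in Eso26 and the oxidative phosphorylation and squamous lists in OE33 came inside the central range (percentiles 95.2, 3.02 and 29.9), and fatty acid oxidation in OE33 moved outside it (percentile 0.50), as did the columnar list (1.04). At a −log10 q of at least 10, 2595 Eso26 and 3167 OE33 peaks remained. The shared part of Eso26 peaks was 7.62% with at least 0.5 of each peak covered, 9.26% with summits within 100 bp, 8.13% with both lists at a −log10 q of at least 10, 13.8% with equal numbers of the strongest peaks and, chosen after seeing the data, 5.3% among the 1000 strongest peaks of each list. Cutting both lists also removes weaker partners of strong peaks, so the lower shares do not show that stronger peaks agree less. Against the full OE33 list, the strongest of the 5 groups of Eso26 peaks had a share of 24.3%. Other scalings of list medians and the removal of unplaced contigs were also added after seeing the data. On assembled chromosomes only, the shared part of Eso26 peaks was 18.2%. No replicate could be left out, since each condition has 1 library. The shared fit pairs siPPARG with control by cell line. No paired analysis was possible within a line. The planned test of expression near peaks was not run, since no hg19 annotation was used here.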

Other observations

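The 2 control libraries differed at many genes. The values below compare single libraries of lines grown in different media, scaled together by TMM, and the genes named were chosen after their values were seen. Of 11211 genes, 2407 were at least 2-fold higher in OE33 and 1826 in Eso26. PPARG was 11.6-fold higher in the OE33 control (130 against 11.2 CPM, counting interval of the ratio 10.2 to 13.3). Of 19 textbook PPAR targets, 10 were at least 2-fold higher in OE33 and 2 in Eso26; AQP3 was 135-fold higher in OE33 (11357 against 118 counts). Of 22 fatty acid synthesis genes, 6 were at least 2-fold higher in OE33 and 1 in Eso26. SCD was 3.05-fold higher in OE33, while FASN differed by 1.20-fold. Of 23 cholesterol genes, 1 was at least 2-fold higher in OE33 and 5 in Eso26.

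The lines also differed in epithelial and immune programmes. Of 20 gastrointestinal transcription factor genes, 10 were at least 2-fold higher in the Eso26 control and 2 in the OE33 control. CDX2, the intestinal homeobox factor gene, had 3911 counts in Eso26 and 240 in OE33, and HNF4A had 5271 and 2. The columnar and intestinal list went both ways, with 8 of 18 genes at least 2-fold higher in Eso26 and 7 in OE33. The intestinal brush border gene VIL1 had 20313 and 18 counts, and the intestinal cadherin gene CDH17 had 14093 and 7, while the keratin gene KRT7 had 30 and 24317. In the OE33 control, 23 of 30 interferon genes and 15 of 17 NF-kB genes were at least 2-fold higher than in Eso26; IFIT1 was 19.4-fold and CXCL8 67.7-fold higher. The EGF-receptor ligand gene EREG had 42136 counts in OE33 and 35 in Eso26.

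PPARG peaks were unevenly spread along the genome. The densest 1 Mb windows in OE33 were chromosome 17 from 36000001 to 37000000 (hg19), with 56 peaks against 3 in Eso26, and chromosome 7 from 102000001 to 103000000, with 46 against 2. Median fold enrichments there were 6.03 and 6.04, below the list's median of 6.71. The densest Eso26 window was chromosome 19 from 1000001 to 2000000, with 51 peaks against 26 in OE33. Chromosome 19 held 7.86% of Eso26 and 3.46% of OE33 peaks, and chromosome 7 held 4.81% and 8.40%. Each line had 1 list, and the control library used for calling is not known. These regional differences between the lines therefore cannot be attributed to PPARG binding.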
